A study of Mus musculus with 9 samples.

How the data were processed

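Liver RNA of mice was sequenced in 9 libraries, 3 each from sham-operated mice, mice with bile duct ligation (BDL) and ligated mice given ligustilide (BDL+LIG). Per the labels' protocols, total RNA was extracted from liver with TRIzol, measured on a NanoDrop instrument and made into libraries with the VAHTS Universal V6 kit. The submitters' processing notes name fastp, HISAT2 version 2.1.0, DESeq2 and the mouse build GRCm39. The gene annotation and the counting program are not given in the sources used here. The values are FPKM (fragments scaled to transcript length and to the mapped fragments of the library), as the authors deposited them in 1 table of 21470 genes with a column for each of the 9 libraries, tied to the samples by their titles. Group and replicate number were taken from the titles. The genome used here for GC content is an earlier mouse build than that of the table, so no coordinates are given and genes are named by the symbols in the table.

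FPKM carry no counts, but a gene's values in different libraries are whole multiples of what 1 fragment is worth. Comparing low genes between libraries gave the relative depths and from these whole fragments for 19446 of 19449 genes with a value above 0 in at least 2 libraries (99.98%, within 0.02 fragments). Alb, Apoe and COX1 were not resolved. In simulated data 98.03% of 18890 genes were recovered exactly. The recovered totals, 30893221 to 37381966 fragments per library, leave out the unresolved genes. They were used for depth, for a comparison of the libraries of each group by chi-square and for the alternative with voom. The ratio of values to fragments also gave each gene's relative length.

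The main test was limma 3.58.1 (lmFit and eBayes with trend) in R 4.3.3 on log2(FPKM + 1), with all 9 libraries in 1 fit and a coefficient per group. Genes with at least 1 FPKM in at least 3 libraries were tested (10142), p-values were adjusted by Benjamini and Hochberg over these genes within each comparison, and 0.05 was the threshold. The comparisons were BDL against sham, BDL+LIG against BDL, BDL+LIG against sham, and the 3 groups together. An exact permutation test of 3 against 3 cannot give a two-sided p below 0.1, so the tests rest on the spread shared across genes. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 38 of 43 lists with at least 5 tested members. With an estimated correlation 0 lists in the first 2 comparisons and 1 in the third were called, against 29, 12 and 27 with the preset one (29, 13 and 28 at an unadjusted p under 0.05). Fry called 25, 7 and 25 lists, not all the same. In BDL+LIG against BDL it lost 9 of 12 and gained 4. Lists can share genes, so calls are linked, and 18 members were not in the table.

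The 43 lists covered collagens and fibrillar matrix, stellate cells and myofibroblasts, matrix proteases, the TGF-beta pathway, cholangiocytes, Kupffer cells, monocytes and macrophages, neutrophils, T and NK cells, B and plasma cells, endothelium, cytokines and chemokines, the acute phase, bile acid synthesis and transport, nuclear receptors, cytochrome P450, NRF2 and AhR targets, iron, fatty acid oxidation, lipogenesis, cholesterol synthesis, urea cycle, hepatocyte secreted proteins, glucose metabolism, pericentral and periportal zones, cell cycle, unfolded protein response, p53 targets, interferon response, MHC class II, male-biased and female-biased genes, circadian clock, immediate early genes, red blood cells, exocrine pancreas, adipose tissue, mesothelium, oxidative phosphorylation, and autophagy and lysosome. Named genes followed a rule, and some genes it names are not reported here. It took the 8 largest rises and the 8 largest falls of BDL against sham and of BDL+LIG against BDL, among called genes whose libraries did not overlap and whose mean was at least 5 FPKM in a group, leaving out clones, predicted genes and pseudogenes. It also took up to 4 members of each described list with the smallest p, the 5 genes per direction with the largest opposite changes, and a fixed set: Acta2, Col1a1, Col1a2, Col3a1, Timp1, Tgfb1, Krt7, Krt19, Spp1, Cyp7a1, Cyp8b1, Slc10a1, Abcb11, Abcc4, Tnf, Il1b, Il6, Ccl2, Cd68, Alb, Hmox1, Nqo1 and Cyp1a1. The groups, tests, lists, this rule and the alternatives not marked as added were fixed before the data were examined.

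Alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 FPKM, median-of-ratios scaling, rescaling to TPM, quantile normalization, rescaling to a common total without the 20 most abundant genes, eBayes robust or without trend, the 2 compared groups alone, the replicate number as a block, a log2 change of at least 1, camera with an estimated correlation, fry, and each library left out in turn. Added after seeing the data were removal of a trend in gene length, or in length and GC content, from each library (loess, span 0.4), voom on the recovered fragments with and without median-of-ratios scaling, and weights per group. For genes called in opposite directions, LIG libraries unchanged from BDL were simulated 100 times, and for genes still past the threshold against sham, LIG libraries at the BDL or the sham means.

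The tests were run on simulated data of 10142 genes with 200 changed. At log2 changes of 0.5, 1 and 2, limma recovered 9, 62.7 and 95.5% for BDL against sham, 13.4, 73.1 and 98.5% for BDL+LIG against BDL and 17.9, 82.1 and 97% for BDL+LIG against sham, with 3, 1 and 6 unchanged genes called. A simulated length trend gave 1221 calls in BDL+LIG against BDL and, in limma after its removal, 0. In BDL against sham a shifted list was called up and 0 other lists were called by camera. Recovery, GC content and figures used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.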

Results

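The series measured RNA in mouse liver after bile duct ligation (BDL), an operation that blocks bile flow and leads to cholestatic liver injury and fibrosis. It asked how ligustilide (LIG) changed liver gene expression in ligated mice. Ligustilide is a phthalide from the volatile oil of Angelica and Ligusticum roots. There were 3 groups of 3 liver libraries: sham, BDL and BDL with LIG (BDL+LIG). The design text gives the LIG dose as 10 mg/kg, whereas the titles of the LIG samples carry the number 20, so the dose is left open. Nothing in the labels says that each library came from a separate mouse. The p-values then measure only the spread between these libraries, which may be technical. Values are means ± SD over the 3 libraries of a group in FPKM as the authors deposited them. Changes are differences of log2(FPKM + 1) ± SE from limma, with an adjusted p over the 10142 genes tested, and they understate the change of genes near 1 FPKM.

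Whole fragment numbers could be recovered from the deposited values. They summed to 31930106, 31328897 and 30893221 in sham libraries 1 to 3 and to 37143966, 37381966 and 32248922 in the BDL libraries. The BDL+LIG libraries held 36912320, 35541178 and 35867275. The deepest library held 1.21 times the fragments of the shallowest. No 2 libraries of a group agreed within sampling noise, with a mean chi-square per gene of 14.86 to 221.71 and a median of 2.57 to 24.14. This comparison covers the counting error of fragments alone, and the most abundant genes carry the means. The first principal component carried 67.8% of the variance and placed the sham libraries apart from the ligated ones. The second, with 15%, placed BDL apart from BDL+LIG. In limma's test over the 3 groups 5161 of 10142 genes differed. Sham library 1 stood apart from the others of its group, at 34.5 on the second component against -6.3 and -12.5. Its Pearson correlations with sham 2 and 3 across genes were 0.974 and 0.964, while that of sham 2 with sham 3 was 0.989. Across genes, which are not independent replicates, the BDL libraries correlated at 0.993 to 0.996 and the BDL+LIG libraries at 0.983 to 0.988. The median SD of a gene was 0.246 on the log2 scale in sham, 0.098 in BDL and 0.147 in BDL+LIG. Mitochondrially encoded transcripts took 12.59, 10.57 and 16.83% of the summed FPKM in sham, 9.76, 9.2 and 8.3% in BDL and 5.86, 8.58 and 7.2% in BDL+LIG.

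**Figure D1:**
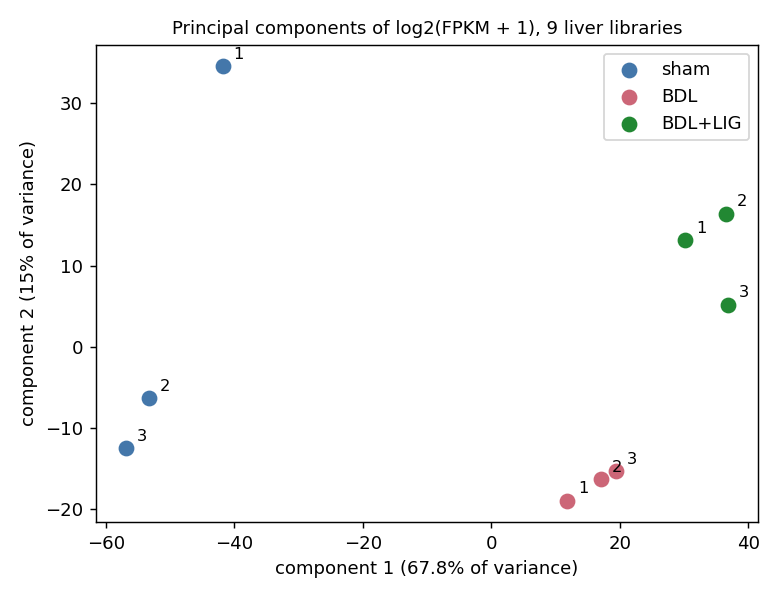
Principal components of log2(FPKM + 1) over the 10142 tested genes, with each point a library, coloured by group and numbered by replicate. Component 1 (67.8% of the variance) parts the sham from the ligated libraries, and sham library 1 lies at 34.5 on component 2 (15%).

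The comparison of BDL with sham measured the effect of the ligation. Genes of collagen and fibrillar matrix, bile duct epithelium, macrophages, chemokines and the acute phase rose in ligated livers. Genes of bile acid synthesis, fatty acid oxidation and cytochrome P450 metabolism, together with transcripts that are more abundant in male liver, were lower as groups. Camera called these groups at its preset correlation, and 0 lists with an estimated one. In limma, 3008 of 10142 genes changed, of which 2322 rose and 686 fell. Of these, 951 changed at least by 1 on the log2 scale (712 up, 239 down). The 8 largest rises were those of Lcn2 (7.21 ± 0.51), Ly6d (5.39 ± 0.53), Orm2 (5.19 ± 0.50), Saa2 (4.93 ± 0.59), Cd14 (4.81 ± 0.29), D17H6S56E-5 (4.77 ± 0.24), Sprr1a (4.54 ± 0.37) and S100a11 (4.42 ± 0.23). Their adjusted p ran from 1.65e-06 to 0.000183. Lcn2 encodes lipocalin-2, which binds bacterial siderophores. Saa2 encodes a serum amyloid A, Orm2 an orosomucoid and Cd14 a coreceptor for bacterial lipopolysaccharide. The 8 largest falls were those of the steroid-metabolising gene Hsd3b5 (-7.40 ± 0.16), the major urinary protein genes Mup7 (-7.08 ± 0.49), Mup15 (-6.93 ± 0.44), Mup11 (-6.89 ± 0.55), Mup17 (-6.44 ± 0.49) and Mup18 (-5.80 ± 0.36), the sulfotransferase gene Sult2a8 (-6.27 ± 0.32) and the alpha-1 antitrypsin gene Serpina1e (-5.77 ± 0.27), with adjusted p from 2.54e-09 to 1.36e-05. Saa, Orm, Mup and Serpina1 genes have near-identical paralogs, so how fragments were divided among the members of each family is uncertain.

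Matrix genes rose after ligation. Among 21 tested collagen and fibrillar matrix genes, 17 rose, 0 fell and 4 did not pass (17 and 0 adjusted over the list alone; camera adjusted p = 9.63e-06, and adjusted p = 0.407 with an estimated correlation). Col1a1, a chain of type I collagen, averaged 11.6 ± 1.92 against 1.24 ± 1.08 FPKM (2.59 ± 0.33, adjusted p = 0.000277). Col1a2 averaged 9.89 ± 2.3 against 1.68 ± 1.09 FPKM (2.09 ± 0.32, adjusted p = 0.00104). Col3a1, of type III collagen, averaged 22.6 ± 3.72 against 3.67 ± 2.31 FPKM (2.46 ± 0.39, adjusted p = 0.00117). The basement membrane collagen gene Col4a1 averaged 11.7 ± 0.97 against 1.82 ± 0.415 FPKM (2.17 ± 0.15, adjusted p = 6.07e-06). Of 16 matrix proteases and their inhibitors, 13 rose, 0 fell and 3 did not pass (13 and 0 adjusted over the list alone; camera adjusted p = 3.81e-06, and adjusted p = 0.172 with an estimated correlation). Timp1, which inhibits matrix metalloproteinases, averaged 8.89 ± 1.33 against 0.147 ± 0.0181 FPKM (3.10 ± 0.25, adjusted p = 1.43e-05). Mmp14 and Mmp7 rose by 1.64 ± 0.11 and 2.81 ± 0.30 (adjusted p = 5.95e-06 and 8.59e-05). In the TGF-beta pathway 12 of 19 genes rose and none fell, with 13 rises adjusted over the list alone (camera adjusted p = 0.000432, and adjusted p = 0.292 with an estimated correlation). Tgfb1 averaged 7.45 ± 0.842 against 3.01 ± 0.943 FPKM (1.10 ± 0.22, adjusted p = 0.00437). Ccn2, the connective tissue growth factor gene, averaged 3.86 ± 0.955 against 0.419 ± 0.183 FPKM (1.77 ± 0.18, adjusted p = 5.75e-05). In the list of hepatic stellate cells and myofibroblasts 7 of 17 rose and none fell (7 up and 0 down adjusted over the list alone), but the list did not pass (camera adjusted p = 0.12). Its rises include Mgp (2.39 ± 0.39) and Vim (1.60 ± 0.26) (adjusted p from 0.00127 to 0.00138), and 4 genes rose with a trend in gene length removed. Acta2, the smooth muscle actin of myofibroblasts, was not past the threshold at 3.36 ± 1.28 against 2.02 ± 1.79 FPKM (0.66 ± 0.40, adjusted p = 0.25), but passed without sham library 1 at a log2 change of 1.10.

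Duct epithelial and myeloid cell markers rose with ligation. Of 20 genes of cholangiocytes and ductular cells, 19 rose, 0 fell and 1 did not pass (19 and 0 adjusted over the list alone; camera adjusted p = 1.85e-10, and adjusted p = 0.172 with an estimated correlation). The keratin gene Krt7 averaged 9.62 ± 2.27 against 0.601 ± 0.341 FPKM (2.73 ± 0.21, adjusted p = 9.89e-06). Krt19 averaged 14 ± 3.9 against 1.67 ± 0.72 FPKM (2.49 ± 0.27, adjusted p = 9e-05). Spp1, which encodes osteopontin, averaged 472 ± 89.9 against 21.5 ± 7.35 FPKM (4.42 ± 0.33, adjusted p = 9.44e-06). Of the markers of Kupffer cells, of monocytes and macrophages, and of neutrophils, 12 of 14, 21 of 23 and 5 of 5 rose and none fell (13, 21 and 5 adjusted over the list alone). All 3 lists were called up (camera adjusted p = 0.000141, 1.74e-08 and 0.0011), and adjusted p = 0.218, 0.268 and 0.172 with an estimated correlation. Among them rose Vsig4 (1.91 ± 0.23), Trem2 (3.13 ± 0.16), Chil3 (3.31 ± 0.27), S100a8 (3.17 ± 0.31) and the macrophage lysosomal marker Cd68 (2.03 ± 0.28), with adjusted p from 1.65e-06 to 0.000486. Cytokines, chemokines and adhesion molecules followed, of which 20 rose, 1 fell and 3 did not pass (21 and 1 adjusted over the list alone; camera adjusted p = 8.61e-09, and adjusted p = 0.167 with an estimated correlation). The monocyte chemoattractant gene Ccl2 averaged 26.1 ± 2.94 against 1.08 ± 0.565 FPKM (3.74 ± 0.23, adjusted p = 2.86e-06). Il1b averaged 2.02 ± 0.355 against 0.458 ± 0.142 FPKM (1.05 ± 0.19, adjusted p = 0.00219). Icam1 averaged 27 ± 1.16 against 6.07 ± 0.459 FPKM (1.98 ± 0.12, adjusted p = 2.75e-06). Tnf and Il6 were too low to test. Tnf averaged 0.955 ± 0.226 FPKM in BDL and 0.245 ± 0.12 in sham. Il6 was listed at 0 in the 3 sham libraries and at 0, 0.172 and 0.252 FPKM in the BDL libraries.

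Acute phase genes, which hepatocytes transcribe in inflammation, rose almost throughout, with 27 of 28 up, 0 down and 1 not past the threshold (27 up adjusted over the list alone). Their median change was 2.05 against 0.16 over all tested genes (camera adjusted p = 2.46e-10, and adjusted p = 0.218 with an estimated correlation). Lcn2 averaged 7243 ± 957 against 57.3 ± 41.7 FPKM. Saa2 averaged 6001 ± 1203 against 221 ± 116 FPKM, and Steap4 (3.16 ± 0.22) rose with them (adjusted p = 6.64e-06).

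Bile acid synthesis was lower as a group. Of 17 genes, 3 rose, 10 fell and 4 did not pass (3 and 10 adjusted over the list alone; camera adjusted p = 9.41e-05, and adjusted p = 0.172 with an estimated correlation), and the list was called down. Cyp8b1, the sterol 12-alpha-hydroxylase, averaged 23.6 ± 1.51 against 126 ± 20.2 FPKM (-2.36 ± 0.13, adjusted p = 2.26e-06). Cyp7b1, the oxysterol 7-alpha-hydroxylase, averaged 11 ± 0.307 against 129 ± 36.9 FPKM (-3.40 ± 0.19, adjusted p = 1.99e-06). Akr1d1 rose (1.45 ± 0.18, adjusted p = 0.000242). Cyp7a1, the rate-limiting enzyme of the classical pathway, was not past the threshold at 26.3 ± 4.05 against 16.2 ± 13.5 FPKM (0.93 ± 0.44, adjusted p = 0.14), but passed without sham library 1 at 1.53. Bile acid and lipid transporters moved both ways, with 7 of 17 up and 6 down (7 and 7 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.125). The sinusoidal uptake carrier gene Slc10a1 fell and averaged 127 ± 5.39 against 250.1 ± 22.8 FPKM (-0.97 ± 0.12, adjusted p = 0.000174). Slco1a1, another, averaged 0.942 ± 0.145 against 60.7 ± 6.8 FPKM (-4.99 ± 0.30, adjusted p = 2.94e-06). Slc51b, a subunit of the basolateral bile acid exporter, rose and averaged 29.5 ± 2.71 against 0.816 ± 0.767 FPKM (4.17 ± 0.31, adjusted p = 9.89e-06). The canalicular exporter gene Abcb11 averaged 70.6 ± 1.04 against 49 ± 17.2 FPKM (0.57 ± 0.19, adjusted p = 0.0463). That call was lost in limma with median-of-ratios scaling, with quantile normalization, in the fit of the 2 groups alone and without any single one of the 6 BDL or BDL+LIG libraries or sham library 2 or 3, at log2 changes of 0.43 to 0.58. Abcc4, a basolateral exporter gene, was too low to test, at 0.421 ± 0.0767 FPKM in BDL and 0.0769 ± 0.0287 in sham. Of the nuclear receptor and bile acid sensing genes 1 rose and 4 fell of 17 (1 and 4 adjusted over the list alone; camera adjusted p = 0.00199, and adjusted p = 0.382 with an estimated correlation). The falls include Nr1h4 (-0.65 ± 0.11), which encodes the bile acid receptor FXR, and Cebpa (-1.10 ± 0.19) (adjusted p from 0.00174 to 0.00192).

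Lists of hepatocyte metabolism were called down as well. Of 27 cytochrome P450 drug metabolism genes, 5 rose, 10 fell and 12 did not pass (5 and 13 adjusted over the list alone; camera adjusted p = 4.76e-06, and adjusted p = 0.167 with an estimated correlation). They include falls of Cyp2c29 (-2.16 ± 0.18) and Cyp2f2 (-1.94 ± 0.16) and a rise of Fmo5 (2.03 ± 0.20) (adjusted p from 1.67e-05 to 4.67e-05). Of 26 genes of fatty acid oxidation and PPAR-alpha targets, 4 rose, 11 fell and 11 did not pass (4 and 13 adjusted over the list alone; camera adjusted p = 4e-07, and adjusted p = 0.167 with an estimated correlation). The fatty acid binding protein gene Fabp1 (-3.80 ± 0.62) fell (adjusted p = 0.00129). Transcripts more abundant in male mouse liver had the lowest median of the 38 lists with a set test, with 15 of 18 down and 0 up (15 down adjusted over the list alone). Their median change was -3.20 (camera adjusted p = 4.38e-21, and adjusted p = 0.0508 with an estimated correlation). Hsd3b5 went from 205 ± 41.5 to 0.203 ± 0.106 FPKM. Mup3 went from 9464 ± 1552 to 259 ± 56.3 (-5.19 ± 0.29, adjusted p = 1.99e-06). The sex of the mice is not given in the sources used here. Proteins that hepatocytes secrete were nearer to the other genes, with 4 up and 4 down of 31 (the same numbers adjusted over the list alone). Their median of -0.08 turned to 0.01 in TPM and was -0.34 with median-of-ratios scaling. The call down (camera adjusted p = 0.00269, and adjusted p = 0.218 with an estimated correlation) was lost with quantile normalization. Albumin (Alb) was not past the threshold at 18150 ± 2088 against 28770 ± 6960 FPKM (-0.64 ± 0.28, adjusted p = 0.115). It passed without sham library 3 at -0.86, and its direction turned under quantile normalization. With median-of-ratios scaling 12 of these secreted protein genes fell and 2 rose, and 1, 2 and 2 rose in the bile acid synthesis, P450 and fatty acid oxidation lists. With a trend in gene length removed 11 secreted protein genes and 17 fatty acid oxidation genes fell, and without sham library 1 there were 8 secreted protein falls and 5 bile acid synthesis rises. The stress enzyme gene Hmox1 averaged 71.2 ± 2.54 against 19.2 ± 2.74 FPKM (1.84 ± 0.16, adjusted p = 2.11e-05). Nqo1 averaged 7.51 ± 0.507 against 2.3 ± 0.777 FPKM (1.39 ± 0.18, adjusted p = 0.000297). Cyp1a1 was too low to test, at 0.0701 ± 0.0485 FPKM in BDL, 0.253 ± 0.0759 in BDL+LIG and 0.205 ± 0.0683 in sham.

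In each gene named here as risen or fallen (required of the largest changes), the BDL libraries lay wholly on one side of sham, as 45% of tested genes did (10% by chance). Over all tested genes the median log2 change was 0.16, and the changes are to be read against that median. It moved to -0.03 with median-of-ratios scaling (1539 up, 1421 down) and with quantile normalization (1510 up, 1402 down). The share of rises was then 52 and 51.9% instead of 77.2%. The count of 3008 was 4628 without sham library 1, 1901 without BDL library 2, 1883 without BDL library 3 and 1838 among genes of at least 5 FPKM on average.

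The comparison of BDL+LIG with BDL measured the effect of LIG in ligated mice. At its preset correlation camera called the lists of acute phase proteins, of the unfolded protein and integrated stress response and of male-biased liver genes lower with LIG. Each of these calls was lost with an estimated correlation, and fry kept only the second. Endothelial and TGF-beta pathway transcripts were higher. Fibrillar collagen genes Col1a1, Col1a2 and Col3a1, the myofibroblast gene Acta2 and the duct genes Krt7 and Krt19, which mark the fibrosis and ductular reaction of the model, did not pass the threshold in either direction. Camera called 12 lists at its preset correlation, 0 with an estimated one, and each of the other 9 splits of these 6 libraries gave at least 12 (24 at most). Of the 12, fry kept the unfolded protein and integrated stress response, endothelial and TGF-beta pathway lists and lost 9. In limma, 1194 of 10142 genes changed, of which 1012 rose and 182 fell. Of these, 109 changed at least by 1 on the log2 scale (82 up, 27 down). The 8 largest rises were those of the acyl-CoA thioesterase gene Acot3 (2.14 ± 0.30), Txnip (1.81 ± 0.22), the translation repressor Eif4ebp2 (1.78 ± 0.26), the G protein regulator Rgs16 (1.71 ± 0.20), Slc10a5 (1.67 ± 0.42), the fatty acid desaturase Scd1 (1.65 ± 0.41), Ddi2 (1.61 ± 0.39) and the interleukin-6 receptor Il6ra (1.59 ± 0.41). They had adjusted p from 0.00697 to 0.035. The 8 largest falls were those of Mup17 (-2.49 ± 0.49), Mup14 (-2.35 ± 0.42), Saa2 (-2.32 ± 0.59), Mup3 (-2.14 ± 0.29), Mup11 (-1.96 ± 0.55), the prostaglandin D synthase Ptgds (-1.71 ± 0.22), the mitochondrially encoded ATP6 (-1.62 ± 0.30) and the serum amyloid P gene Apcs (-1.43 ± 0.24), with adjusted p from 0.00697 to 0.0457.

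**Figure D2:**
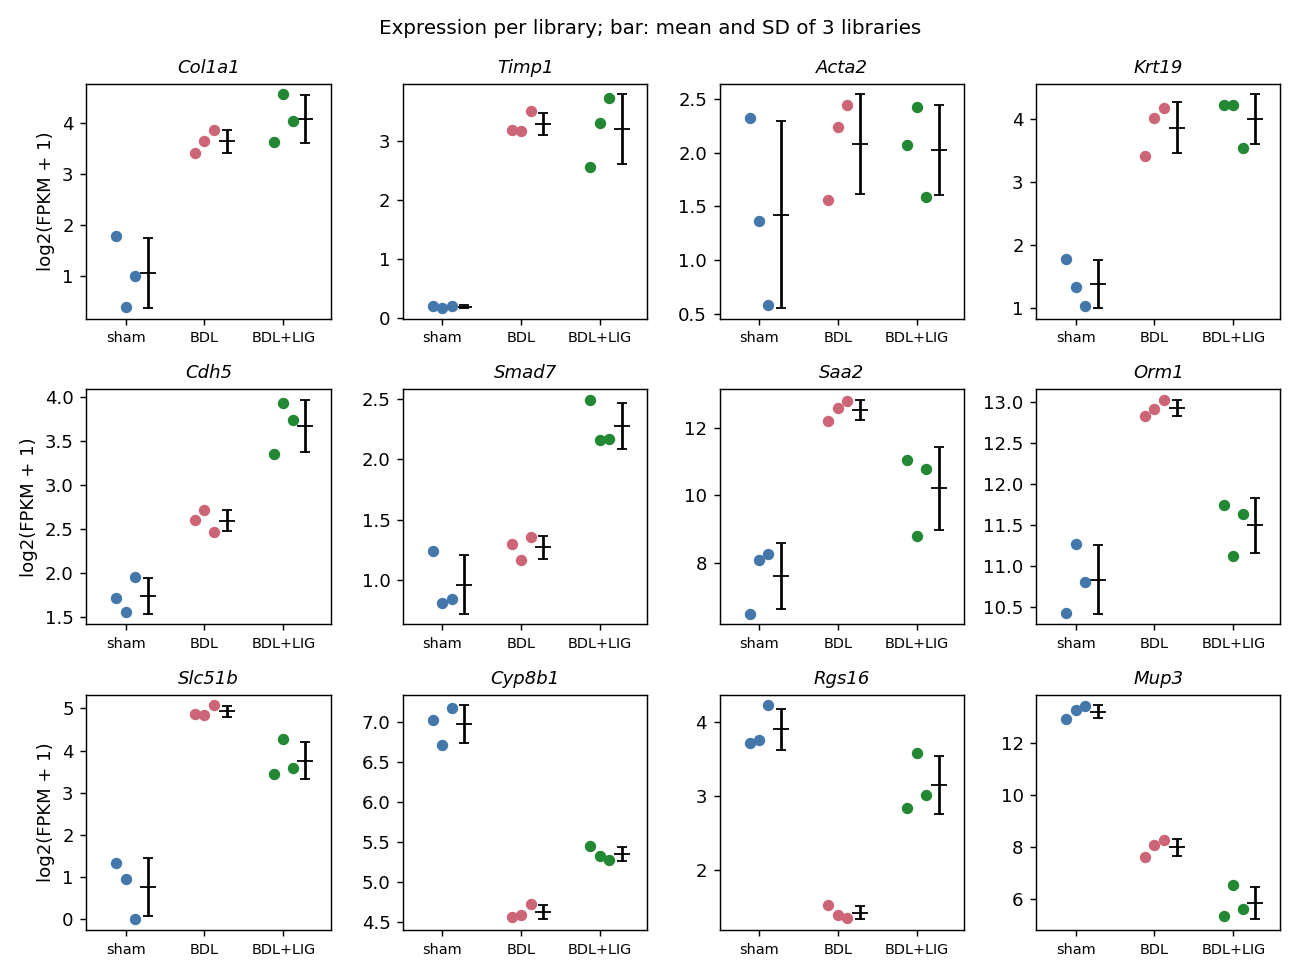
Expression of 12 genes per library as log2(FPKM + 1), with points for libraries, a bar for the group mean and whiskers for the SD over 3 libraries. Saa2 and Orm1 rose with ligation and fell with LIG, Cyp8b1 and Rgs16 fell and then rose, Cdh5 and Smad7 were highest with LIG, and the BDL and BDL+LIG points of Acta2, Timp1 and Krt19 overlap.

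Acute phase transcripts were lower with LIG. Of 28 genes 4 fell, 0 rose and 24 did not pass (7 fell adjusted over the list alone). The median change was -0.63 against 0.18 over all tested genes (camera adjusted p = 1.52e-12, and adjusted p = 0.364 with an estimated correlation). Fry did not call the list (adjusted p = 0.141). Saa2 averaged 1441 ± 879.7 against 6001 ± 1203 FPKM (-2.32 ± 0.59, adjusted p = 0.0337). Orm1, an orosomucoid, averaged 2944 ± 635 against 7758 ± 537 FPKM (-1.42 ± 0.24, adjusted p = 0.0131). Apcs averaged 199 ± 61.8 against 525 ± 86.7 FPKM (-1.43 ± 0.24, adjusted p = 0.0128). Saa4 averaged 115 ± 32.8 against 278 ± 42.9 FPKM (-1.29 ± 0.27, adjusted p = 0.02). Lcn2, named here after its values were seen, was not past the threshold at 2947 ± 1504 against 7243 ± 957 FPKM (-1.44 ± 0.51, adjusted p = 0.0853). The median of the list against the BDL mean was -0.33, -1.24 and -0.34 in BDL+LIG libraries 1 to 3. The group median moved to -0.31 without library 2, and 10 of the genes fell without sham library 1. Among the neutrophil markers S100a9 fell (-1.11 ± 0.29, adjusted p = 0.0389) and 4 of 5 did not pass (2 fell adjusted over the list alone; camera adjusted p = 0.0181, and adjusted p = 0.364 with an estimated correlation). This list call was lost with median-of-ratios scaling, with quantile normalization and with a trend in gene length removed, where S100a9 did not pass either (-0.82 ± 0.29, adjusted p = 0.125). Chemokine and cytokine genes did not pass as a list (3 up and 2 down of 24; 5 up and 2 down adjusted over the list alone; camera adjusted p = 0.315). The list passed without BDL+LIG library 3, where its relative median (its median less that of all tested genes) was -0.25 instead of -0.09. Ccl2 averaged 29.1 ± 7.77 against 26.1 ± 2.94 FPKM (0.13 ± 0.23, adjusted p = 0.728). Il1b averaged 1.76 ± 0.74 against 2.02 ± 0.355 FPKM (-0.16 ± 0.19, adjusted p = 0.59). Tnf, not tested, averaged 0.804 ± 0.41 FPKM. Il6 was listed at 0, 0.0222 and 0.0884 FPKM in the BDL+LIG libraries.

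The list of the unfolded protein and integrated stress response was lower with LIG. Of its 19 genes, 1 rose, 7 fell and 11 did not pass (2 and 8 adjusted over the list alone; camera adjusted p = 1.13e-06, and adjusted p = 0.0558 with an estimated correlation). In TPM 4 fell. The calcium-binding chaperone Calr averaged 403 ± 45 against 705 ± 9.15 FPKM (-0.81 ± 0.14, adjusted p = 0.013). The disulfide isomerase gene Pdia4 averaged 63.4 ± 3.89 against 95.9 ± 3.23 FPKM (-0.59 ± 0.12, adjusted p = 0.0187). Sdf2l1 and Creld2 changed by -0.87 ± 0.16 and -0.78 ± 0.18 (adjusted p = 0.0146 and 0.0247). In the male-biased list 3 of 18 fell and none rose (5 adjusted over the list alone; camera adjusted p = 0.000607, and adjusted p = 0.364 with an estimated correlation). The call was lost in camera with quantile normalization (adjusted p = 0.115) and with fry (adjusted p = 0.212). Those that fell were Mup3, at 61 ± 28.2 against 259 ± 56.3 FPKM, Mup20 (-1.34 ± 0.27) and Cyp4a12a (-1.36 ± 0.25) (adjusted p from 0.0145 to 0.0177 for the latter genes), in the direction in which they had moved with ligation. Proteins that hepatocytes secrete were called down, and of 31, 1 rose, 3 fell and 27 did not pass (1 and 3 adjusted over the list alone; camera adjusted p = 0.000598, and adjusted p = 0.364 with an estimated correlation). The falls include Pon1 (-0.63 ± 0.12) and the coagulation factor F9 (-0.50 ± 0.11) (adjusted p from 0.0162 to 0.024). The median of that list, -0.10, turned to 0.05 in TPM and to 0.06 with quantile normalization and was -0.32 with median-of-ratios scaling, and its call was lost with the length trend removed. Alb averaged 26730 ± 4211 against 18150 ± 2088 FPKM (0.55 ± 0.28, adjusted p = 0.202). In the pericentral hepatocyte list 1 gene, Rgn (-0.75 ± 0.16), fell of 14 (adjusted p = 0.02), also adjusted over the list alone. The list was called down (camera adjusted p = 0.0064, and adjusted p = 0.285 with an estimated correlation), and this was lost with quantile normalization and with a mean of at least 5 FPKM. Red blood cell transcripts were lower, with 2 of 5 down (4 adjusted over the list alone; camera adjusted p = 8.42e-05, and adjusted p = 0.364 with an estimated correlation). They were the alpha globin genes Hba-a1 (-0.95 ± 0.26) and Hba-a2 (-0.97 ± 0.28), with adjusted p from 0.044 to 0.0478. They are near-identical copies whose separate levels are uncertain, and neither passed with the length trend removed. Without sham library 1 the falls in the male-biased, secreted protein, red blood cell and oxidative phosphorylation lists were 5, 6, 4 and 5. Mitochondrially encoded transcripts, to which ATP6 belongs, took 5.86, 8.58 and 7.2% of the summed FPKM with LIG and 9.76, 9.2 and 8.3% in BDL. In the oxidative phosphorylation list of nuclear genes 1 gene, Atp5b (0.50 ± 0.14), rose and 1, Ndufa1 (-0.52 ± 0.14), fell of 23 (adjusted p from 0.0432 to 0.0442; 0 up and 0 down adjusted over the list alone). Neither gene passed with the length trend removed (0.46 ± 0.13 and -0.22 ± 0.12, adjusted p = 0.0694 and 0.294), nor Atp5b with median-of-ratios scaling (0.28 ± 0.16, adjusted p = 0.286), nor Ndufa1 in TPM. The median of the list was 0.05 and its mean -0.03, and camera called it down (camera adjusted p = 0.044, and adjusted p = 0.917 with an estimated correlation). That call was lost in TPM, with quantile normalization, with no filter, with a mean of at least 5 FPKM, with a pseudocount of 0.1, without the 20 most abundant genes in the scaling and without sham library 3, BDL library 1 or BDL+LIG library 3 (relative medians of -0.13, -0.07 and -0.12, and -0.13 with all libraries). The median was 0.20 in TPM and turned to -0.17 with median-of-ratios scaling, and the direction that camera gave turned with the length trend removed.

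Endothelial transcripts were higher with LIG, 14 of 18 rising and none falling (17 adjusted over the list alone; camera adjusted p = 1.08e-07, and adjusted p = 0.364 with an estimated correlation). The VE-cadherin gene Cdh5 averaged 11.9 ± 2.55 against 5.05 ± 0.501 FPKM (1.08 ± 0.17, adjusted p = 0.012). Pecam1 averaged 5.74 ± 0.812 against 2.71 ± 0.292 FPKM (0.86 ± 0.14, adjusted p = 0.0124). The endoglin gene Eng averaged 15 ± 4.24 against 5.84 ± 0.349 FPKM (1.20 ± 0.20, adjusted p = 0.0128). Gpr182 averaged 9.74 ± 2.94 against 3.59 ± 0.0968 FPKM (1.19 ± 0.20, adjusted p = 0.013). In BDL against sham the same list had 2 rises and 1 fall (2 and 0 adjusted over the list alone; camera adjusted p = 0.726). Its median, 0.13, was 0 with median-of-ratios scaling, 0.23 in TPM and turned to -0.16 with quantile normalization. In the TGF-beta pathway 11 of 19 genes rose and none fell (14 adjusted over the list alone; camera adjusted p = 1.1e-05, and adjusted p = 0.364 with an estimated correlation). They include Smad6 (0.96 ± 0.12, adjusted p = 0.00697) and Smad7 (1.00 ± 0.16, adjusted p = 0.012), which encode inhibitory Smads that restrain the pathway. The receptor gene Tgfbr2 (0.80 ± 0.14) rose too (adjusted p = 0.0134), and the ligand gene Tgfb1 averaged 15.7 ± 4.34 against 7.45 ± 0.842 FPKM (0.95 ± 0.22, adjusted p = 0.0273). With the length trend removed 5 genes of the list rose and with median-of-ratios scaling 5, at medians of 0.31 and 0.43 instead of 0.59, and the list stayed called up. In the stellate cell list 7 of 17 rose (9 adjusted over the list alone; camera adjusted p = 0.0165, and adjusted p = 0.917 with an estimated correlation). They include Colec11 (1.41 ± 0.28), Reln (1.11 ± 0.20) and Pdgfrb (0.73 ± 0.16) (adjusted p from 0.014 to 0.0212). Of this list 2 rose with the length trend removed and 4 with median-of-ratios scaling. That list call was lost without sham library 1, without BDL+LIG library 2 (relative medians of 0.43 and 0.31, and 0.43 with all libraries) and among genes of at least 5 FPKM on average. The last setting also ended the collagen call. Of the collagen and fibrillar matrix genes 5 of 21 rose and none fell (11 adjusted over the list alone; camera adjusted p = 0.00359, and adjusted p = 0.917 with an estimated correlation). Among them were Col4a1 (0.68 ± 0.15), Col14a1 (1.10 ± 0.26) and Bgn (1.05 ± 0.28) (adjusted p from 0.0238 to 0.0394). With the length trend removed, and with median-of-ratios scaling, 0 of the 21 genes passed in limma (8 and 11 rose at an unadjusted p under 0.05), although camera still called the list up. Without sham library 1 11 rose. Reln and Pdgfrb were lost with the trend removed. Tgfb1 was lost with median-of-ratios scaling.

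Apart from Tgfb1, which rose, the fibrosis and duct genes named in advance did not pass with LIG. Col1a1 averaged 16.5 ± 5.79 against 11.6 ± 1.92 FPKM (0.43 ± 0.33, adjusted p = 0.383). Col1a2 averaged 14.5 ± 5.48 against 9.89 ± 2.3 FPKM (0.47 ± 0.32, adjusted p = 0.336). Col3a1 averaged 37 ± 16.8 against 22.6 ± 3.72 FPKM (0.60 ± 0.39, adjusted p = 0.315). Acta2 averaged 3.18 ± 1.18 against 3.36 ± 1.28 FPKM (-0.05 ± 0.40, adjusted p = 0.938). Timp1 averaged 8.74 ± 3.73 against 8.89 ± 1.33 FPKM (-0.09 ± 0.25, adjusted p = 0.822). Krt7 averaged 9.19 ± 1.14 against 9.62 ± 2.27 FPKM (-0.04 ± 0.21, adjusted p = 0.904). Krt19 averaged 15.4 ± 4.11 against 14 ± 3.9 FPKM (0.13 ± 0.27, adjusted p = 0.758). Spp1 averaged 314 ± 128 against 472 ± 89.9 FPKM (-0.67 ± 0.33, adjusted p = 0.19). The lists of matrix proteases and of cholangiocytes did not pass (5 up and 0 down of 16, and 1 up and 1 down of 20). There were 7 up and 0 down adjusted over the list alone in the first and 1 and 1 in the second (camera adjusted p = 0.185 and 0.995). With the length trend removed 1 matrix protease gene rose, and with median-of-ratios scaling 0 passed in limma (7 up at an unadjusted p under 0.05). The duct transcription factor gene Elf3 fell (-0.73 ± 0.17, adjusted p = 0.0253). Kupffer cell and macrophage lists did not pass either (1 up and 0 down of 14, and 2 up and 0 down of 23; 1 and 1 up adjusted over the list alone; camera adjusted p = 0.315 and 0.922). Adgre1, which encodes the macrophage marker F4/80, rose (1.41 ± 0.28, adjusted p = 0.0169). Cd68 was not past the threshold (0.34 ± 0.28, adjusted p = 0.43). Without sham library 1, 8, 4 and 4 genes rose in the protease, cholangiocyte and Kupffer cell lists. With 3 libraries a group these values leave room for changes in either direction.

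Bile acid and lipid genes moved singly. In bile acid synthesis 1 of 17 genes rose and none fell (1 up and 0 down adjusted over the list alone). It was Cyp8b1, at 39.8 ± 2.64 against 23.6 ± 1.51 FPKM (0.73 ± 0.13, adjusted p = 0.0141). The call was lost with median-of-ratios scaling. Cyp7a1 averaged 36.8 ± 12.4 against 26.3 ± 4.05 FPKM (0.42 ± 0.44, adjusted p = 0.529). Among the transporters 1 rose and 1 fell of 17 (3 up and 1 down adjusted over the list alone). Slc51b fell and averaged 13 ± 4.54 against 29.5 ± 2.71 FPKM (-1.17 ± 0.31, adjusted p = 0.0408), a call lost with the length trend removed. Slc10a1 (0.10 ± 0.12, adjusted p = 0.57) and Abcb11 (70.5 ± 2.11 against 70.6 ± 1.04 FPKM, adjusted p = 0.997) did not pass. Abcc4, not tested, averaged 0.767 ± 0.0772 FPKM. Camera called neither list (adjusted p = 0.922 and 0.891), nor those of P450 metabolism, fatty acid oxidation and lipogenesis (adjusted p = 0.324, 0.185 and 0.315). Fatty acid oxidation passed without BDL+LIG library 3 (relative median of 0.09 instead of 0.05). In the P450, fatty acid oxidation and lipogenesis lists 2 of 27, 5 of 26 and 3 of 20 genes rose and none fell (1, 5 and 5 up and 0, 0 and 1 down adjusted over the list alone). Among the rises were Cyp2c29 (0.95 ± 0.18), the acyl-CoA thioesterases Acot1 (1.29 ± 0.21) and Acot2 (0.97 ± 0.17) and the peroxisomal enzyme Ehhadh (0.91 ± 0.20) (adjusted p from 0.0128 to 0.0224). With the length trend removed, and with median-of-ratios scaling, 0 lipogenesis genes passed in limma (4 and 4 up and 2 and 1 down at an unadjusted p under 0.05). Fatty acid oxidation had 3 rises with the trend removed and 8 without sham library 1, where 7 lipogenesis, 4 P450 and 6 transporter genes rose. Scd1 averaged 1249 ± 609.5 against 393 ± 165 FPKM. Hmox1 and Nqo1 did not pass (0.21 ± 0.16, adjusted p = 0.388 and 0.09 ± 0.18, adjusted p = 0.746).

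**Figure D3:**
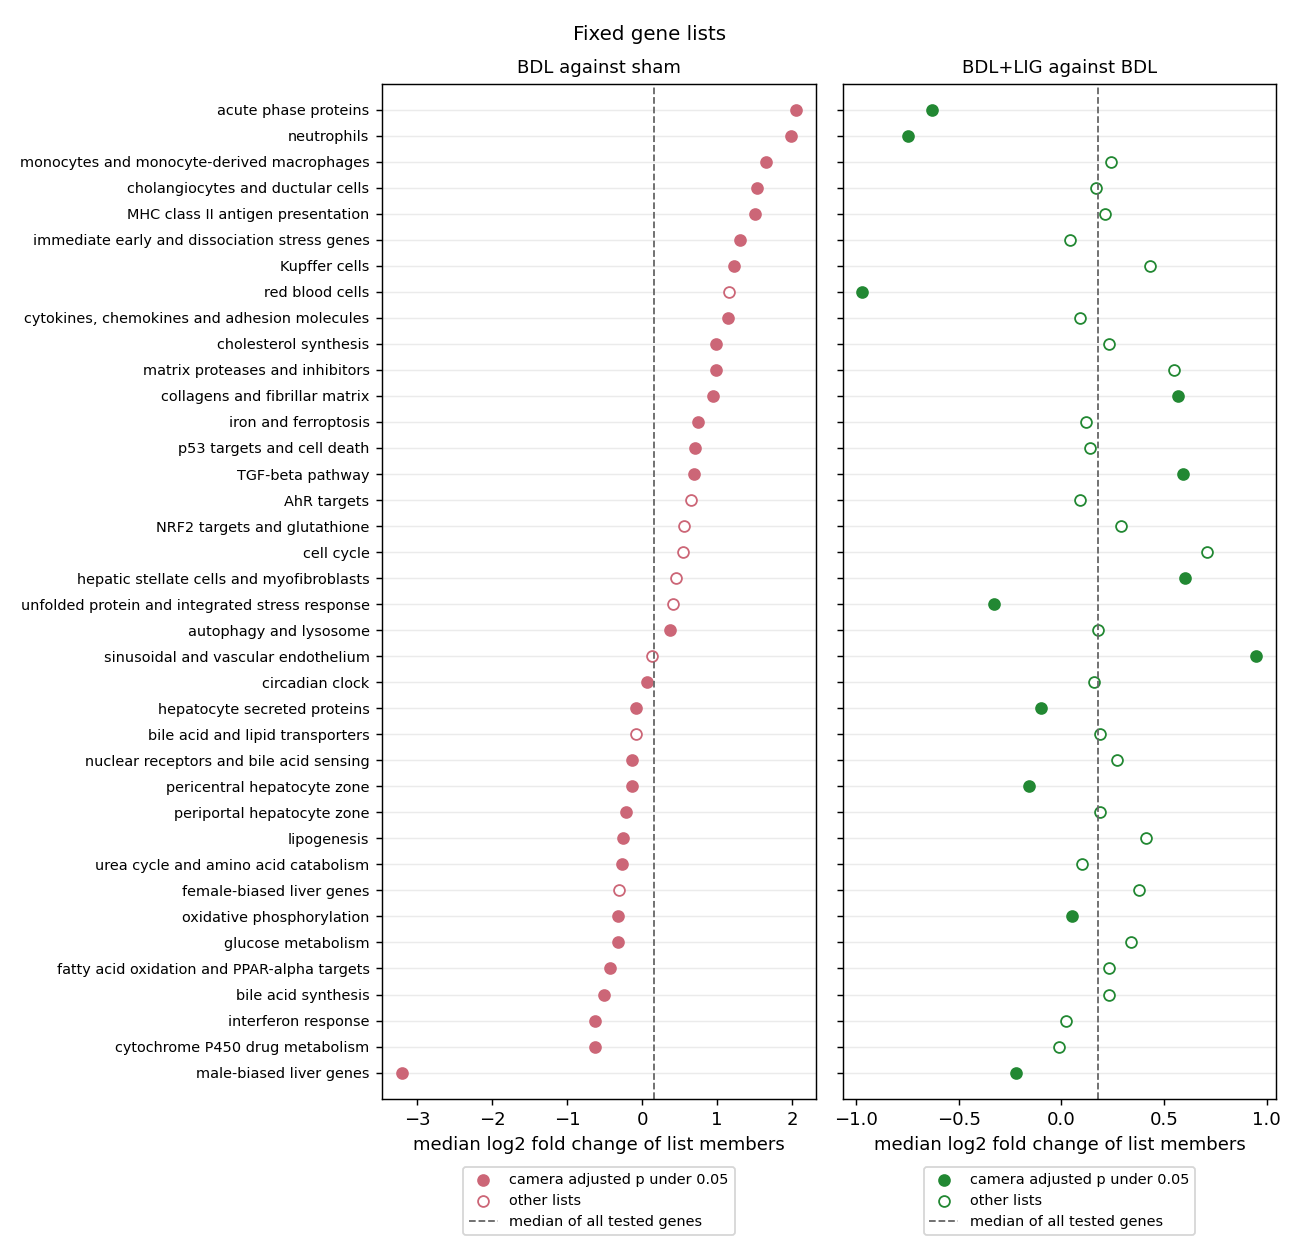
Median log2 fold change of the tested members of each of the 38 gene lists with a set test, for BDL against sham (left) and BDL+LIG against BDL (right), with filled points for lists that camera called and a dashed line at the median of all tested genes (0.16 and 0.18). Acute phase, neutrophil and red blood cell lists lie on opposite sides of the line in the panels, and male-biased genes lie left of it in both; medians of hepatocyte secreted proteins and oxidative phosphorylation turn sign with the scaling on the right.

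The change with LIG ran with gene length, as the deposited values imply it. In 5 groups of genes of equal size, from the shortest to the longest, the median log2 change was -0.12, 0.08, 0.19, 0.28 and 0.34. In them 31, 115, 205, 305 and 356 genes rose and 121, 31, 17, 7 and 6 fell. Spearman's rank correlation of the change with length, across genes, was 0.48, against 0.04 for BDL against sham. With that trend removed from each library, a setting chosen after the data were seen, 496 genes passed (267 up, 229 down), of which 349 were among the 1194 in the same direction. Of the 8 largest rises and falls, those of Slc10a5, Scd1, Il6ra, Saa2 and Mup11 no longer passed. They went from 1.67, 1.65, 1.59, -2.32 and -1.96 to 1.43 ± 0.36, 1.36 ± 0.38, 1.39 ± 0.37, -2.13 ± 0.57 and -1.82 ± 0.50, with limma adjusted p from 0.0524 to 0.0684. With median-of-ratios scaling Slc10a5, Scd1, Ddi2, Il6ra and Mup11 did not pass, at 1.48, 1.43, 1.41, 1.39 and -2.09 (adjusted p from 0.0516 to 0.0641).

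**Figure D4:**
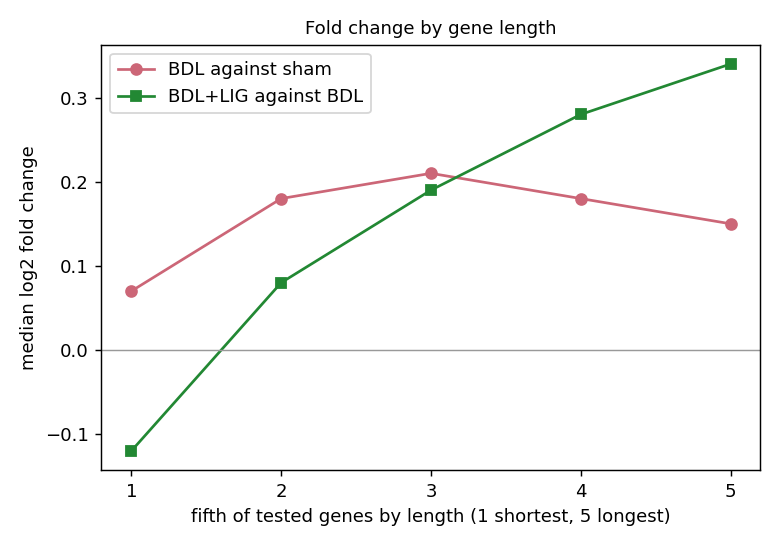
Median log2 fold change of tested genes in 5 equal groups by relative length, 1 (shortest) to 5 (longest), for BDL against sham (circles) and BDL+LIG against BDL (squares). The second climbs from -0.12 to 0.34 and the first lies between 0.07 and 0.21.

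In each gene named as changed with LIG (required of the largest changes), the BDL+LIG libraries lay wholly on one side of BDL, as 51.2% of tested genes did (10% by chance). Without BDL library 1, 2 or 3 limma called 40, 0 and 68 genes (2310 at an unadjusted p under 0.05 without library 2). Without BDL+LIG library 1, 2 or 3 it called 492, 193 and 223, and without sham library 1 it called 3137. The fit pools the spread of the 3 groups, so sham libraries, which are not in this comparison, enter its p-values. The median of all tested genes was 0 with median-of-ratios scaling (340 up, 346 down) and with quantile normalization (575 up, 531 down), 0.33 in TPM (1828 up, 98 down) and 0.28 rescaled to a common total without the 20 most abundant genes (1849 up, 121 down). The share of rises among called genes ran from 49.6 to 94.9% beside 84.8% in the values as deposited.

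The comparison of BDL+LIG with sham measured how ligated livers given LIG differed from livers without ligation. Matrix, duct, macrophage and endothelial genes were higher than in sham as lists, and male-biased genes lower. In limma 5335 genes differed, 4430 higher and 905 lower, and 1704 by at least 1 on the log2 scale. Col1a1 averaged 16.5 ± 5.79 against 1.24 ± 1.08 FPKM (3.03 ± 0.33, adjusted p = 6.26e-05). Timp1 averaged 8.74 ± 3.73 against 0.147 ± 0.0181 FPKM (3.01 ± 0.25, adjusted p = 1.27e-05). Krt19 averaged 15.4 ± 4.11 against 1.67 ± 0.72 FPKM (2.62 ± 0.27, adjusted p = 4.22e-05). Collagen and fibrillar matrix genes were higher in 19 of 21, cholangiocyte genes in 19 of 20, monocyte and macrophage genes in 21 of 23 and endothelial genes in 17 of 18, with none lower (20, 19, 21 and 17 adjusted over the list alone). Camera called these 4 lists up (adjusted p = 1.04e-05, 4.22e-07, 8.76e-06 and 0.00126), and adjusted p = 0.43, 0.235, 0.43 and 0.43 with an estimated correlation. Acute phase genes were higher in 20 of 28 (20 adjusted over the list alone; camera adjusted p = 0.0125, and adjusted p = 0.557 with an estimated correlation). Saa2 averaged 1441 ± 879.7 against 221 ± 116 FPKM. With median-of-ratios scaling 11 were higher. The list call was lost without sham library 1 and without BDL+LIG library 1 (relative medians of 0.75 and 0.60 instead of 0.95). Male-biased genes were lower in 16 of 18 and higher in 1 (the same numbers adjusted over the list alone). This was the 1 list called with an estimated correlation as well (camera adjusted p = 1.47e-21, adjusted p = 0.048 with an estimated correlation). The split was 2374 higher and 2463 lower with median-of-ratios scaling, 2273 and 2247 with quantile normalization and 5620 and 535 in TPM (49.1, 50.3 and 91.3% higher beside 83%). In all, 2765 genes passed among those of at least 5 FPKM on average.

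Whether LIG reversed ligation changes was asked of genes called in both comparisons. There were 133 in opposite directions, 74 raised by ligation and lowered with LIG and 59 lowered and then raised, and 315 in the same direction. With the length trend removed 111 were opposite and 95 the same, and with median-of-ratios scaling 106 and 120. Among the first were Saa2 (4.93 ± 0.59 with ligation and -2.32 ± 0.59 with LIG), Apcs (1.59 ± 0.24 and -1.43 ± 0.24), Orm1 (2.08 ± 0.24 and -1.42 ± 0.24), Ptgds (3.74 ± 0.22 and -1.71 ± 0.22) and Slc51b (4.17 ± 0.31 and -1.17 ± 0.31). Among the second were Rgs16 (-2.46 ± 0.20 and 1.71 ± 0.20), Cyp2c29 (-2.16 ± 0.18 and 0.95 ± 0.18), the autophagy kinase gene Ulk1 (-1.17 ± 0.19 and 0.92 ± 0.19), Txnip (-0.90 ± 0.22 and 1.81 ± 0.22) and Abca8a (-1.22 ± 0.24 and 0.90 ± 0.24), which did not pass with LIG under trend removal, median-of-ratios scaling or quantile normalization. Of 2322 genes ligation raised 2136 (92%) stayed above sham with LIG, and of 686 it lowered 492 (71.7%) stayed below. Both tests share the 3 sham libraries, so overlap is partly built in. In 100 simulations with LIG at the BDL means the shares were 84.7% (82.5 to 86.3) and 79.3% (75.6 to 83.6), and at the sham means at most 0.102%. Simulations omit the LIG shift of all genes (median 0.18, 0.2 and 0.13 in these sets), so cannot show reversal.

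Both comparisons hold the same BDL libraries, which gives opposite changes by chance. In 100 simulations of unchanged LIG libraries around the BDL means, 0.03 genes on average and 1 at most were called in opposite directions. Independent lists of these sizes would share 110.1 in opposite directions (41.7 raised then lowered and 68.5 lowered then raised) and 244 in the same direction. The simulation leaves out real effects, so almost no gene can be called in BDL+LIG against BDL and a count near 0 was set in advance. It cannot show how many of the 133 come from sharing, and the independent lists leave out the shared libraries. With 3 BDL libraries no parts of 2 were possible, so part of any excess may come from sharing. Across genes the covariance of the 2 changes was 0.00576 against -0.00748 simulated with the BDL spread (difference 0.0132). The pooled spread, which sham widens, gave -0.0224 (0.0281). Without BDL library 2, 0 opposite calls were left in limma (2310 genes passed at an unadjusted p under 0.05 in BDL+LIG against BDL), and without sham library 1 there were 288.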

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

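The removal of length or length and GC trends, voom and the weights per group were chosen after the data were seen. The 3008 genes of BDL against sham stayed within 1.5 times of that count except with a mean of at least 5 FPKM (1838), a log2 change of at least 1 (951) and single libraries left out (1883 to 4628). The 5335 of BDL+LIG against sham moved to 2765 and 1704 in the same settings (4332 to 6859 without 1 library), and the 5161 among the 3 groups to 2781 (4063 to 7012). The count of 1194 in BDL+LIG against BDL moved furthest. It became 623 with no filter, 575 with a mean of at least 5 FPKM, 686 with median-of-ratios scaling, 1926 in TPM and 1970 without the 20 most abundant genes in the scaling. It became 3433 in the fit of the 2 groups alone, 3507 with weights per group, 109 with a log2 change of at least 1, 496 (267 up, 229 down) with the length trend removed and 470 (255 up, 215 down) with length and GC trends removed. Without 1 library limma called 0 (without BDL library 2; 2310 at an unadjusted p under 0.05) to 3137 (without sham library 1), and voom, which called 1453, shared 1138 of these calls. Fewer genes tested, or a larger change asked for, account for the mean and log2 limits, and for the others the cause was not tested. The 133 opposite calls became 73 with no filter, 257 in the 2-group fits, 15 with the log2 limit and 283 with weights (0 to 288 without 1 library). The covariance of 0.00576 became 0.0256 and 0.0114 with pseudocounts of 0.1 and 0.5, 0.00985 with a mean of at least 5 FPKM, 0.00991 with median-of-ratios scaling and 0.0103 in TPM. It was -0.000697 with quantile normalization, 0.000814 with the length trend removed and 0.000382 with both trends removed (-0.00783 to 0.0244 without 1 library), and the cause was not tested.

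Pairing by replicate number stays open. Deviations from group means correlated across genes at -0.13 to 0 for the same number and -0.07 to 0.11 for others (sham with BDL). BDL with BDL+LIG gave 0.01 to 0.11 and -0.11 to 0.01, and sham with BDL+LIG -0.06 to 0.28 and -0.3 to 0.14. With the number as a block 742 genes (602 up, 140 down) passed in BDL+LIG against BDL, 694 among the 1194.

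Lists called went from 29, 12 and 27 to 0, 0 and 1 with an estimated correlation, and in BDL+LIG against BDL to 19 with no filter, 7 with a mean of at least 5 FPKM and 7 with fry. Without 1 library they ran from 24 to 29, 11 to 14 and 23 to 29. Called lists that turned direction, as the median less that of all tested genes, were hepatocyte secreted proteins in BDL+LIG against BDL (0.0581 with quantile normalization), periportal hepatocyte zone in BDL+LIG against sham (0.0406 with quantile normalization) and oxidative phosphorylation in BDL+LIG against BDL (0.00966 with the length trend removed and 0.0277 with length and GC trends removed). The cause was not tested. Fry, which does not compare a list with other genes, gave the opposite direction to camera for lipogenesis in BDL against sham (the same median of -0.421) and unfolded protein and integrated stress response in BDL+LIG against sham (the same median of -0.457). Of 80 genes named in BDL against sham and 77 in BDL+LIG against BDL, no called gene turned direction. In BDL+LIG against BDL 17 lost their call with the length trend removed, 12 with median-of-ratios scaling, 28 with no filter, 50, 59 and 50 without BDL library 1, 2 and 3, and 18, 28 and 30 without BDL+LIG library 1, 2 and 3. Some genes not past the threshold turned direction, in BDL+LIG against BDL unless named otherwise. With median-of-ratios scaling, the log2 change was -0.088 for Ccl2, -0.074 for Krt19, -0.119 for Slc10a1, -0.0135 for Hmox1 and -0.102 for Nqo1. In TPM it was 0.0697 for Acta2, 0.0408 for Timp1, 0.0997 for Krt7 and 0.148 for Abcb11. With quantile normalization it was 0.0686 for Alb (BDL against sham), -0.000444 for Krt19 and -0.0971 for Nqo1. Without the 20 most abundant genes in the scaling it was 0.0462 for Acta2, 0.0239 for Timp1, 0.0752 for Krt7 and 0.126 for Abcb11. With the length trend removed it was 0.0817 for Timp1 and -0.107 for Nqo1, and with length and GC trends removed 0.0388 and -0.0984. With voom it was 0.0127 for Abcb11. With voom and median-of-ratios scaling it was -0.0986 for Ccl2, -0.0768 for Krt19, -0.119 for Slc10a1, -0.0136 for Hmox1 and -0.124 for Nqo1. Without 1 library they ran, as log2 changes, for Krt19 -0.0974 to 0.361, Acta2 -0.315 to 0.167, Krt7 -0.229 to 0.0821, Abcb11 -0.0261 to 0.0106, Timp1 -0.359 to 0.227 and Ccl2 -0.0777 to 0.237. The cause was not tested.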

Other observations

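Of the tests in this part, those with the length trend removed, with the 20 most abundant genes left out of the scaling and with the hepatocyte secreted list were chosen after the result was seen.

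Further gene groups moved with ligation. Of 24 cholesterol synthesis genes, 17 rose, 0 fell and 7 did not pass (17 and 0 adjusted over the list alone; camera adjusted p = 0.000198, and adjusted p = 0.407 with an estimated correlation). The rises include Hmgcs1 (2.17 ± 0.30) (adjusted p = 0.00047). Interferon response genes were called down. Of 21, 1 rose, 9 fell and 11 did not pass (1 and 10 adjusted over the list alone; camera adjusted p = 3.81e-06, and adjusted p = 0.218 with an estimated correlation). Falls were those of Usp18 (-1.26 ± 0.21) and Ifi44 (-0.88 ± 0.16), among others (adjusted p from 0.00174 to 0.00238). Of 20 p53 targets and cell death genes, 13 rose, 0 fell and 7 did not pass (15 and 0 adjusted over the list alone; camera adjusted p = 7.09e-05, and adjusted p = 0.28 with an estimated correlation). The cell cycle inhibitor gene Cdkn1a (4.35 ± 0.17) and Phlda3 (2.21 ± 0.24) rose (adjusted p from 4.74e-07 to 0.0001). Of 14 immediate early and dissociation stress genes, 10 rose, 0 fell and 4 did not pass (11 and 0 adjusted over the list alone; camera adjusted p = 1.03e-06, and adjusted p = 0.167 with an estimated correlation). They include Atf3 (2.66 ± 0.16) and Jun (2.25 ± 0.17) (adjusted p from 2.85e-06 to 9.16e-06). The clock output gene Dbp and the repressor gene Nr1d1 changed by -2.80 ± 0.22 and -3.26 ± 0.31 (adjusted p = 1.31e-05 and 3.83e-05). In the whole clock list of 17, 5 rose, 6 fell and 6 did not pass (5 and 7 adjusted over the list alone; camera adjusted p = 0.0369, and adjusted p = 0.501 with an estimated correlation). Its mean was -0.31, as in the call down, while its median was 0.06 and turned to -0.16 with median-of-ratios scaling and -0.14 with quantile normalization (0.14 in TPM). The call was lost without sham library 1 (-0.12 less all genes instead of -0.10). Of 23 oxidative phosphorylation genes, 0 rose, 7 fell and 16 did not pass (0 and 7 adjusted over the list alone; camera adjusted p = 2.96e-07, and adjusted p = 0.189 with an estimated correlation). Ndufb5 was among those that fell (-0.62 ± 0.14, adjusted p = 0.00867). Genes of MHC class II antigen presentation were called up. Of 9, 8 rose, 0 fell and 1 did not pass (9 and 0 adjusted over the list alone; camera adjusted p = 0.00248, and adjusted p = 0.409 with an estimated correlation). Among the rises were Lgmn (1.70 ± 0.20) and Ctss (1.96 ± 0.27) (adjusted p from 0.000142 to 0.000508). With median-of-ratios scaling 4 rose, and 14 oxidative phosphorylation genes fell, as they did with the length trend removed and without sham library 1, but 3 in TPM. Without sham library 1, 5 MHC class II genes rose and the list did not pass (median less that of all tested genes of 1.10 instead of 1.34).

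Among the other lists of BDL against sham, camera called up iron and ferroptosis and autophagy and lysosome. Of 20 genes of iron and ferroptosis, 12 rose, 1 fell and 7 did not pass (15 and 1 adjusted over the list alone; camera adjusted p = 0.00849, and adjusted p = 0.167 with an estimated correlation). Of 20 genes of autophagy and lysosome, 10 rose, 2 fell and 8 did not pass (11 and 2 adjusted over the list alone; camera adjusted p = 0.043, and adjusted p = 0.407 with an estimated correlation). With median-of-ratios scaling 6 and 5 genes of the 2 lists rose. Camera called down lipogenesis, urea cycle and amino acid catabolism, glucose metabolism and both hepatocyte zones. Of 20 genes of lipogenesis, 3 rose, 5 fell and 12 did not pass (3 and 5 adjusted over the list alone; camera adjusted p = 0.0491, and adjusted p = 0.597 with an estimated correlation). Of 22 genes of the urea cycle and amino acid catabolism, 2 rose, 5 fell and 15 did not pass (2 and 5 adjusted over the list alone; camera adjusted p = 0.00302, and adjusted p = 0.465 with an estimated correlation). Of 14 genes of glucose metabolism, 1 rose, 4 fell and 9 did not pass (1 and 4 adjusted over the list alone; camera adjusted p = 0.00302, and adjusted p = 0.189 with an estimated correlation). Of 14 genes of the pericentral zone, 1 rose, 3 fell and 10 did not pass (1 and 4 adjusted over the list alone; camera adjusted p = 0.0261, and adjusted p = 0.172 with an estimated correlation). Of 16 genes of the periportal zone, 2 rose, 2 fell and 12 did not pass (2 and 2 adjusted over the list alone; camera adjusted p = 0.0152, and adjusted p = 0.407 with an estimated correlation). Camera did not call the next 6 lists. Of 27 genes of NRF2 targets and glutathione, 14 rose, 5 fell and 8 did not pass (16 and 7 adjusted over the list alone; camera adjusted p = 0.327). Of 5 genes of AhR targets, 3 rose, 1 fell and 1 did not pass (3 and 1 adjusted over the list alone; camera adjusted p = 0.319). Of 12 genes of the cell cycle, 2 rose, 0 fell and 10 did not pass (1 and 0 adjusted over the list alone; camera adjusted p = 0.672). Of 19 genes of the unfolded protein and integrated stress response, 7 rose, 1 fell and 11 did not pass (7 and 1 adjusted over the list alone; camera adjusted p = 0.287). Of 8 genes of the female-biased list, 2 rose, 1 fell and 5 did not pass (2 and 1 adjusted over the list alone; camera adjusted p = 0.219). Of 5 genes of red blood cells, 4 rose, 1 fell and 0 did not pass (4 and 1 adjusted over the list alone; camera adjusted p = 0.534). With median-of-ratios scaling the rises were 2 in the unfolded protein and integrated stress response, 2 in the clock, 2 in red blood cells and 1 each in lipogenesis, the urea cycle, the periportal zone and the cell cycle, and the falls 8 in the urea cycle and 4 in the periportal zone. After removal of the length trend 4 stress response and 2 clock genes rose. Without sham library 1 there were 8 rises in the clock, 4 in the urea cycle and 6 rises and 3 falls in lipogenesis, and in TPM 2 lipogenesis and 3 NRF2 target genes fell. Calls of lipogenesis and both zones were lost with median-of-ratios scaling, quantile normalization, the length trend removed and a mean of at least 5 FPKM (medians less that of all tested genes of -0.48 to -0.23, -0.36 to -0.12 and -0.45 to -0.15). Lipogenesis was lost also with no filter and without the 20 most abundant genes in the scaling. Autophagy and lysosome was lost with median-of-ratios scaling and trend removal (0.15 and 0.19), and the urea cycle and glucose metabolism with quantile normalization (-0.17 and -0.25). The clock was lost with these 3 settings and with no filter (-0.13 to 0.07). Gained were stellate cells with median-of-ratios scaling or no filter (0.32 and 0.31), NRF2 targets with quantile normalization (0.57) and the stress response with quantile normalization or no filter (0.22 and 0.40). Without single libraries calls were lost, with medians less that of all tested genes, for autophagy and lysosome without sham library 1 or 2 or BDL library 1 (0.19, 0.21 and 0.16 instead of 0.21). They were also lost for lipogenesis without sham library 1 or BDL library 2 or 3 (-0.28, -0.41 and -0.36 instead of -0.42), the pericentral zone without sham library 2 or 3 (-0.23 and -0.16 instead of -0.30) and the periportal zone without sham library 1 (-0.33 instead of -0.38). The 5 lists with under 5 tested members had no set test. Of 3 adipose genes 2 fell with ligation (2 adjusted over the list alone), and of 1 exocrine pancreas gene 1 fell. None of 3 T and NK cell, 1 B and plasma cell and 2 mesothelium genes passed, also adjusted over the list alone. The genes that fell were Car3 (-5.24 ± 0.60), Lipe (-0.81 ± 0.13) and Cela2a (-0.92 ± 0.28) (adjusted p from 0.000144 to 0.0327), the last lost without BDL library 1 or 3 or sham library 2 (-0.99, -0.71 and -0.70).

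In BDL+LIG against BDL camera did not call the remaining 16 lists, with adjusted p from 0.128 to 0.961. The genes that rose and fell, with those adjusted over the list alone in parentheses, were for nuclear receptors and bile acid sensing 3 and 0 of 17 (4 and 0), NRF2 targets and glutathione 0 and 1 of 27 (0 and 0), AhR targets 0 and 0 of 5 (0 and 0), iron and ferroptosis 2 and 0 of 20 (2 and 0), cholesterol synthesis 1 and 0 of 24 (1 and 0), urea cycle and amino acid catabolism 1 and 0 of 22 (1 and 0), glucose metabolism 1 and 0 of 14 (1 and 0) and the periportal zone 0 and 0 of 16 (0 and 0). They were, in the same order, for the cell cycle 0 and 0 of 12 (0 and 0), p53 targets and cell death 2 and 1 of 20 (2 and 1), interferon response 0 and 0 of 21 (0 and 0), MHC class II 1 and 0 of 9 (1 and 0), female-biased genes 1 and 0 of 8 (1 and 0), the circadian clock 1 and 0 of 17 (3 and 0), immediate early genes 1 and 0 of 14 (1 and 0) and autophagy and lysosome 5 and 0 of 20 (7 and 0). Among them rose the clock gene Cry2 (0.95 ± 0.21) and the stress-induced Sesn1 (0.94 ± 0.16) (adjusted p from 0.0128 to 0.0223). In limma 0 nuclear receptor genes passed with median-of-ratios scaling or with the length trend removed (4 and 4 up at an unadjusted p under 0.05), and 0 iron and ferroptosis genes with the former (1 up and 2 down unadjusted). Autophagy and lysosome rises were 1 and 3 in these settings, and the single rises in the urea cycle, glucose metabolism and MHC class II were lost in both. Rises without sham library 1 and in TPM were 6 and 5 for nuclear receptors, 5 and 4 for iron, 3 and 4 for cholesterol synthesis and 5 and 3 for the clock. They were 3 and 3 for glucose metabolism, the same for immediate early genes, and 1 and 3 for NRF2 targets. Without single BDL+LIG libraries calls were gained, with medians less that of all tested genes, for the cell cycle without library 1 or 3 (0.92 and 0.64 instead of 0.54), the urea cycle without library 1 (-0.21 instead of -0.08) and nuclear receptors without library 2 (0.19 instead of 0.09). Calls were also gained for the cell cycle with median-of-ratios scaling, quantile normalization, trend removal and no filter, and for matrix proteases with the last 2. They were gained for Kupffer cells with trend removal and for fatty acid oxidation with quantile normalization, trend removal and no filter. With quantile normalization lipogenesis, glucose metabolism and autophagy passed, and with no filter the last 2 and nuclear receptors. Of the lists without a set test, the B and plasma cell gene Jchain (1.14 ± 0.23) rose (adjusted p = 0.02), and no other member passed (2 of 3 T and NK cell genes and 1 of 3 adipose genes rose adjusted over the list alone).

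More genes rose than fell with LIG, and long genes rose. Unequal scaling by the most abundant transcripts was argued against, since with libraries rescaled to a common total the median of all tested genes was 0.28 without the 20 most abundant genes and 0.33 with them (a ratio of 0.78 to 0.89 without 1 library). The scaling of whole libraries stays open, as median-of-ratios scaling, which sets the median near 0 by construction, gave 340 rises and 346 falls, and so does a length trend between libraries that the treatment did not set. With the trend removed 349 of the 1194 genes (29.2%) passed in the same direction, and in the median calls were lost because changes shrank, from a size of 0.60 to 0.34 with standard errors of 0.14 and 0.12. The 9 differences between a BDL+LIG and a BDL library each ran with length (Spearman correlations across genes of 0.32 to 0.53), but sham libraries differed by up to 0.48 among themselves, against 0.16 within BDL and 0.26 within BDL+LIG, and removing the trend also removes any effect of LIG that runs with length, so the 2 cannot be told apart here.

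Acute phase transcripts were lower with LIG, with a median of -0.63. A lower share of hepatocytes as the whole cause was argued against by the 31 hepatocyte secreted genes outside the acute phase list, whose median was -0.1 (-0.17 to -0.05 without 1 library) and, with median-of-ratios scaling, -0.32 beside -0.85, a difference of -0.53 in both (-0.72 to -0.26 without 1 library). A part for it stays open, since that list was itself called down and 14 of 18 endothelial and 7 of 17 stellate cell genes rose, while a length trend as the whole cause was argued against by the median of -0.74 with that trend removed, where 4 members fell, as many as before. BDL+LIG library 2 may set much of the size: the median was -0.31 without it, which is borderline for a loss of over 50% of it, and libraries 1 to 3 lay at -0.33, -1.24 and -0.34. An effect of LIG itself stays open as a hypothesis, along with the part that library 2 plays.

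Sham library 1 stood apart from sham libraries 2 and 3. A swapped label with a ligated library was argued against, since 2 of 48 cholangiocyte and acute phase genes lay nearer to the BDL mean than to the mean of the other sham libraries. A trend in length and GC content as the whole cause was argued against by its lower correlation of 0.971 after both trends were removed (0.964 before), where sham 2 and 3 reached 0.99 (0.989 before). Its deviation from the sham mean ran with length at a Spearman correlation of 0.5 across genes. No biological explanation was tested, and a difference between animals or in sampling stays open.

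Other splits of the libraries were counted for each result of a fit across genes. For the 3 comparisons of 2 groups the 10 splits of 6 libraries are too few for a share under 0.05. The real splits called 3008, 1194 and 5335 genes in limma (1 of 10 as large in each), and the highest other split called 0 in each (1698, 340 and 1410 at most at an unadjusted p under 0.05). Lists called were 29, 12 and 27 with 23, 24 and 24 in the highest other split, and 1, 10 and 1 of the 10 splits gave as many. For BDL+LIG against BDL each split called at least as many lists as the real one. For genes that differed among the 3 groups 1 of 100 splits reached 5161 (highest other 2632), and chance among these libraries can be excluded, though not chance between mice if libraries shared an animal. For opposite calls 3 of 100 splits reached 133, and the highest other, with 2194, points to a structure of the samples. In limma 97 of the 99 other splits gave 0 opposite calls, so the share of splits, set in advance as the bound, bears on whether the groups differ and not on whether LIG reversed changes. The 133 stand beside 110.1 for independent lists. For the covariance 21 of 100 splits reached 0.00576 (highest other 0.0521), and chance cannot be excluded.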
